A study of Mus musculus with 6 samples.

How the data were processed

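Mononuclear cells from mouse liver were profiled by droplet single-cell RNA sequencing, and T cell receptor (TCR) sequences were read from the same cells. The 3 groups were wild-type (WT) mice on a 60% high-fat diet (HFD), WT mice on the same diet with 0.25% hyodeoxycholic acid (HDCA), a bile acid, and mice lacking the Jα18 segment on the diet with HDCA. The knockout mice are called iNKT KO in the labels, because the receptor of invariant natural killer T (iNKT) cells needs that segment. Feeding lasted 12 weeks. Each group had 1 RNA library and 1 TCR library, so there were no replicates, and the number of mice behind a library is not given in the sources used here. The study design and the extraction protocol name a sort for CD45, whereas the treatment text names CD4. B cells alone made up 33.2% to 38.5% of the kept cells of a library, so the cells were not a CD4 sort. The labels state 10000 sorted cells per sample, but 10228 barcodes were present for WT HFD+HDCA. A normal diet named in the study design was not among the samples and was not analysed here.

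The RNA files held deposited counts: unique molecular identifiers (UMIs) per gene and cell barcode, per the file headers from Cell Ranger 8.0.1, for 33696 genes and barcodes the authors had already filtered (lowest total 500 to 502 UMIs). Barcode and gene names, in other files deposited beside them, were text. The TCR files held counts of UMIs and reads per assembled contig as deposited, and only contigs that the authors' pipeline had marked full-length, productive and of high confidence. Both mm10 and GRCm39 are named as genome builds in the submitters' processing notes, and the gene annotation release is not given in the sources used here, so no coordinates are printed. A table of the GRCm38.p6 assembly was used only to find which genes share a chromosome with Traj18. Although a kit for the 3′ end is named, UMIs on TCR V segments were 2.23, 2.44 and 2.60 times those on TCR constant genes in the 3 RNA libraries, so the 5′ part of the transcripts was read. Depth was 44332213 UMIs for WT HFD, 70776925 for WT HFD+HDCA and 46600746 for iNKT KO HFD+HDCA. Eif2s3y, a Y-linked gene, was seen in 40.7%, 41.3% and 40.0% of barcodes, and Xist had 2, 4 and 1 UMIs.

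Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, and doublets called by Scrublet in each library (scanpy 1.11.5) were removed. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were chosen within libraries without TCR and immunoglobulin segments, Xist and Y-linked genes. These gave 30 principal components, a graph of 20 neighbours and 31 Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). The 10 genes with the highest fold over all other cells, with 20 counts per 1000000 UMIs (CPM) added to both sides, named a cluster when at least 3 were markers of a class and more than of any other class. Class names therefore mean similarity of markers. The CD4 T class, for example, was led by Foxp3 and Ctla4 of regulatory T cells, and 12 clusters stayed unnamed. A cell was iNKT-type when a productive TCR α contig joined TRAV11 or TRAV11D to TRAJ18. Other αβ T cells had both chains and no such contig. A clonotype was a set of nucleotide CDR3 sequences of both chains, and expansion was compared after 100 random draws to the smallest library.

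Counts were summed per class and library and given as CPM of that class, with no further normalization. With 1 library per group there is no error between mice, so no test of a difference between groups was run and no genes were called changed. Genes at least 2-fold apart were counted only to look at their chromosomes, without calling them changed. Checks of explanations are described with the results flagged for a closer look. Ratios carry conditional exact 95% intervals, levels exact Poisson and shares exact Clopper-Pearson 95% intervals. All of these, and the limits that a count of 0 allows (3 counts), cover counting error only. The comparisons were WT HFD+HDCA against WT HFD, and iNKT KO HFD+HDCA against WT HFD+HDCA. No ratio of the knockout to WT HFD was taken, apart from 1 check of Slc15a2, because genotype and diet differ together, although shares and levels of all 3 libraries are given side by side. Genes were named by a rule. In each of the 4 largest named classes it took the 3 highest and the 3 lowest ratios among genes with at least 100 UMIs and a ratio of at least 1.5 either way, and in iNKT-type cells the 6 highest and lowest with at least 50 UMIs. TCR and immunoglobulin segments, gene models, mitochondrial, ribosomal protein, sex-linked and free-RNA genes were left out of the rule. Traj18, Trav11 and 10 receptor or cytokine genes were reported in any case, and up to 4 members with at least 50 UMIs were taken as examples of a described list. The 29 gene lists were described by the median log2 ratio of members with at least 20 UMIs, the number of members higher and lower, and the percentile of the median among 10000 random lists matched on expression. List intervals came from 1000 Poisson resamplings of the counts. The percentile describes these libraries and is not a test. The groups, comparisons, gene lists, naming rules and a first set of alternative settings were chosen before the data were examined.

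That set covered contig and cell filters, iNKT and clonotype definitions, doublets, resolution, clustering of each library alone, marker gates, TMM factors (edgeR 4.0.16, R 4.3.3), thinning of each cell to 2000 UMIs, equal weight per cell, other totals and count minimums. Alternatives chosen after seeing the data were clusters of the naive T and NK classes on their own, leaving out the cell with most UMIs of a gene, leaving out the largest clonotype of each library or of WT HFD alone, and free RNA in NK and B cells clustered without the cell filter. The calculation of the gene comparison was tested on simulated data drawn from the B cells. These were Poisson counts from 1 pooled profile, as the intervals assume, without cells or differences between libraries. They check the calculation and say nothing about error between cells, mice or libraries. Of 50 genes simulated 2-fold higher, 98% passed a ratio of 1.5, against 0.349% of 9465 unchanged genes, and intervals covered the true ratio for 95.6% of unchanged and 93.8% of 192 changed genes, but for only 86% of the 50 genes simulated 2-fold higher. Of 200 null lists, 4% fell outside the central 95% of random lists. Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.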

Results

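The data are gene counts and TCR sequences of single CD45-positive cells from mouse liver, collected to ask how HDCA, a bile acid added to a high-fat diet, acts on liver immune cells and what it does without iNKT cells. The groups were WT HFD, WT HFD+HDCA and iNKT KO HFD+HDCA, with 1 RNA library and 1 TCR library each. The RNA libraries held 6479, 10228 and 7153 barcodes, of which 6166, 9678 and 6815 cells were kept, at a median of 5610.5, 5463.5 and 5116 UMIs per cell. Doublets made up 4.01%, 4.85% and 4.26% of barcodes. A TCR contig was deposited for 2650, 3811 and 2318 barcodes, at a median of 7, 7 and 8 UMIs per contig. With 1 library per group, every comparison is between single libraries, and the intervals cover counting error alone.

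The targeted segment was present in both WT libraries and undetected in the knockout. Traj18 (ENSMUSG00000076911) had 172 UMIs in WT HFD, 160 in WT HFD+HDCA and 0 in iNKT KO HFD+HDCA. Among kept cells its level was 3.85 CPM (3.28 to 4.50) and 2.24 CPM (1.89 to 2.63) in the WT libraries, and the 0 in the knockout allows up to 0.0698 CPM. Within iNKT-type cells, Traj18 was at 46.6 CPM in WT HFD and 29.5 CPM in WT HFD+HDCA. Trav11, the V segment of the iNKT receptor, had 80, 88 and 0 UMIs in the 3 libraries, and its absence in the knockout allows up to 0.0698 CPM of kept cells. MAIT-type cells, which join TRAV1 to TRAJ33, numbered 2, 2 and 0 among cells with an α chain, where 0 allows a share of up to 0.149% in the knockout.

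iNKT-type cells made up like shares of the T cells in both WT libraries and were nearly undetected in the knockout. They were 15.1% of the 2353 cells with an α chain in WT HFD (13.7% to 16.6%) and 14.6% of 3386 in WT HFD+HDCA (13.4% to 15.9%). In the knockout 1 of 2012 such cells was iNKT-type, a share of 0.0497% (0.00126% to 0.277%). That contig rested on 2 UMIs, and with at least 3 UMIs per contig the share was 0. The invariant CDR3 sequence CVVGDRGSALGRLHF was carried by 92.7% and 93.1% of the WT iNKT-type cells. Their β chains used TRBV13-2, part of the Vβ8 family, in 46.5% and 50.1% of cases, against 13.3% and 11.2% among other T cells. The TRBV13, TRBV29 and TRBV1 segments together served 89.2% and 93.4% of iNKT-type β chains, and 38.5%, 34.5% and 41.7% of those of other T cells in the 3 libraries.

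The knockout differed from WT in the whole α repertoire, not in Jα18 alone. Segments TRAJ19 and higher were used by 75.6% of α chains outside iNKT-type cells in WT HFD (73.8% to 77.4%) and by 73.1% in WT HFD+HDCA (71.5% to 74.6%), but by 12.3% of 2145 chains in the knockout (10.9% to 13.8%). Within that range, TRAJ19 to TRAJ49 took 67.2% and 62.4% of chains in WT and 3.54% in the knockout, and TRAJ50 and higher took 8.41%, 10.7% and 8.76%. Segments TRAJ17 and lower took 22.7% and 25.01% of chains in WT and 87.7% in the knockout. The knockout used 35 of the 43 Jα segments seen. Counting each distinct CDR3 once, TRAJ19 and higher took 7.84% of knockout chains, and TRAJ50 and higher took 9.53% and 9.34% in WT but 4.01% in the knockout (3.13% to 5.06%), so expanded clones held up the share of that range per cell. The knockout thus differed from WT both in its lack of iNKT-type cells and in the receptors of its other T cells. The comparisons of the knockout below cannot tell these apart.

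**Figure D1:**
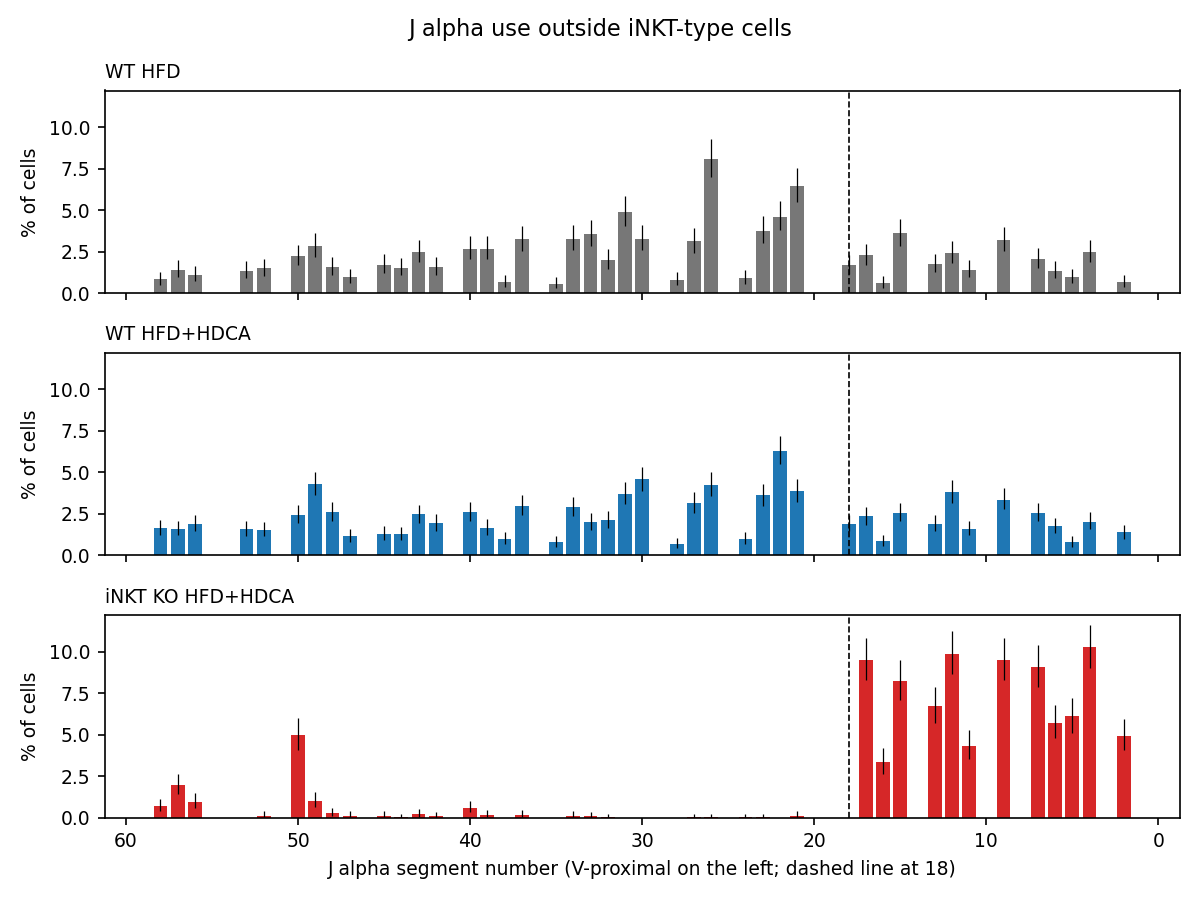
Share of α chains outside iNKT-type cells that used each Jα segment, by segment number (x axis, V-proximal segments on the left), in the 3 TCR libraries. The y axis, labelled % of cells, gives % of α chains with 95% Clopper-Pearson intervals. Segments 19 and higher held 75.6% and 73.1% of chains in the WT libraries and 12.3% in the knockout.

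Outside iNKT-type cells, the WT libraries had like shares of cells in clonotypes of 2 or more, while more WT HFD cells were in large clonotypes, mostly through 1 clone. After drawing 1954 cells per library, cells in clonotypes of 2 or more made up 18.8% of WT HFD, 18.3% of WT HFD+HDCA and 21.6% of iNKT KO HFD+HDCA. Clonotypes of 5 or more cells held 12.0%, 8.34% and 13.2%. The largest clonotype held 82 cells in WT HFD, 31 in WT HFD+HDCA and 41 in the knockout, or 4.20%, 1.09% and 2.08% of cells after drawing. Without the largest clonotype of each library, chosen after seeing the data, clonotypes of 5 or more held 8.12%, 6.996% and 11.2%, and those of 2 or more 15.2%, 17.1% and 19.8%. Among iNKT-type cells, drawn to 353 and so not comparable with the shares above, 7.65% of WT HFD and 4.41% of WT HFD+HDCA were in clonotypes of 2 or more.

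Among cell classes, WT HFD+HDCA had fewer naive T cells and more monocytes than WT HFD. The knockout under HDCA had more ILC1 than WT under HDCA, and smaller CD4 T and CD8 T classes, which leave out the CD4 and CD8 cells of the naive T class. Naive T cells were 15.8% of WT HFD, 10.2% of WT HFD+HDCA and 13.1% of the knockout library, a ratio of 0.646 for HDCA in WT (0.591 to 0.707) and 1.29 for the knockout (1.17 to 1.41). Monocytes were 2.79%, 3.95% and 2.82%, with ratios of 1.41 (1.18 to 1.70) and 0.714 (0.597 to 0.851). ILC1, tissue-resident innate relatives of NK cells, were 2.45%, 2.15% and 5.22%, a ratio of 2.43 for the knockout (2.04 to 2.90). CD4 T cells, a cluster led by Foxp3 and Ctla4, were 4.36%, 4.55% and 2.95% (knockout ratio 0.649, 0.546 to 0.768). CD8 T cells were 5.22%, 5.94% and 4.53% (knockout ratio 0.763, 0.662 to 0.878), and B cells were 33.2%, 33.8% and 38.5% (knockout ratio 1.14, 1.08 to 1.20). NK cells were 8.94%, 9.90% and 9.14%, but their cluster rich in Klrg1 and S1pr5, markers of mature NK cells, held 0.178% and 0.403% of cells in the WT libraries and 3.07% in the knockout. Its first leading gene was Ighg2c, an immunoglobulin gene. It also held most UMIs of the residency genes Zfp683 and Itga1 in knockout NK cells. The larger NK cluster had only 3 of 113 and 9 of 172. When each library was clustered alone, the knockout ratio was 0.690 for B cells, 0.982 for monocytes and 0.930 for CD8 T cells, so these 3 depend on how clusters were drawn. Within the naive T class, the CD8 cluster held 6.49% of WT HFD, 5.57% of WT HFD+HDCA and 7.34% of the knockout, and the CD4 cluster 9.28%, 4.62% and 5.78%. The lower naive T share under HDCA in WT thus lay mostly in the CD4 cluster. Without clusters, cells with any TCR contig were 39.8%, 36.2% and 31.5%, which includes iNKT-type cells (5.34%, 4.66% and 0.0147%). Cells with both chains outside the iNKT type were 29.5%, 27.1% and 26.7%, alike in the HDCA libraries.

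**Figure D2:**
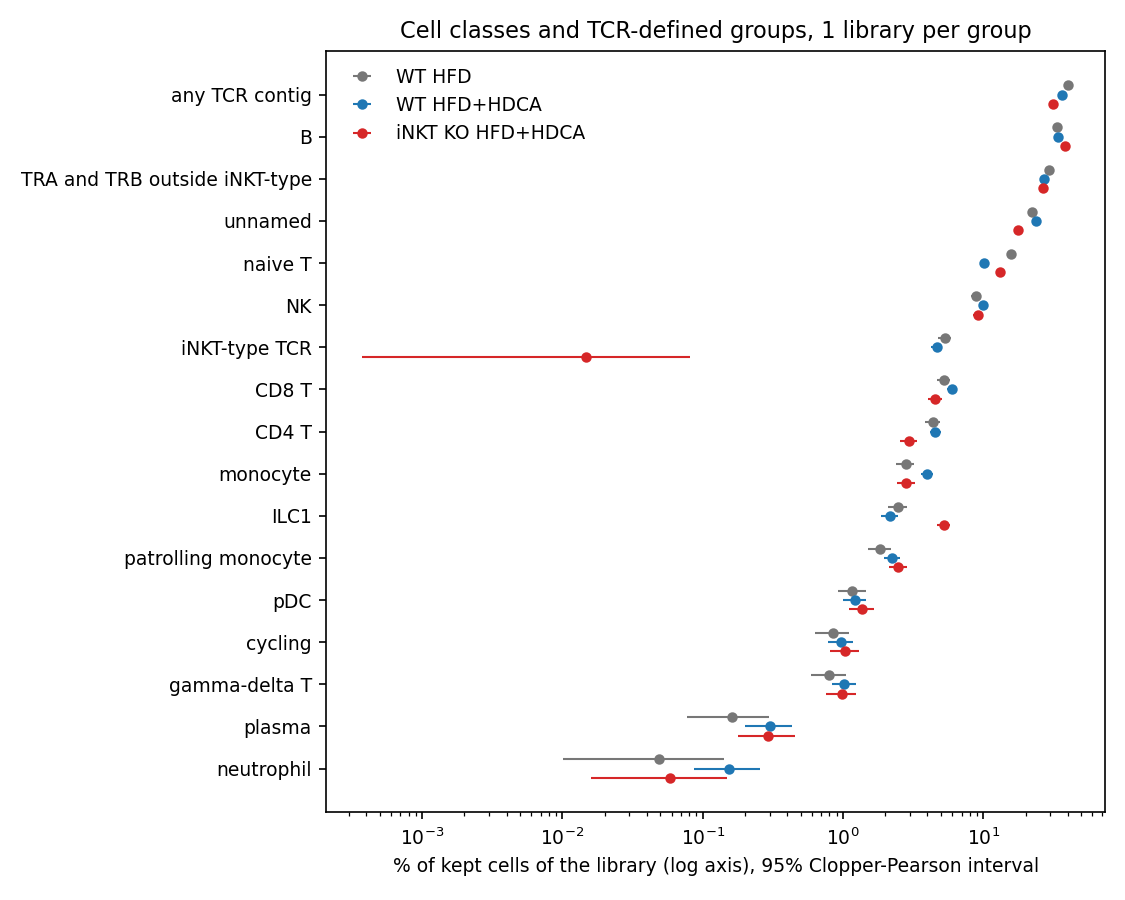
Share of kept cells in each class or TCR-defined group (x axis, %, log axis, with 95% Clopper-Pearson intervals) for the 3 RNA libraries, 1 per group. ILC1 stood at 5.22% in the knockout against 2.15% in WT HFD+HDCA, and naive T cells at 10.2% in WT HFD+HDCA against 15.8% in WT HFD.

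HDCA in WT was compared by the ratio of WT HFD+HDCA to WT HFD. Among genes with at least 100 UMIs, the highest ratio in 3 of the 4 largest classes was that of Slc15a2 (ENSMUSG00000022899), a transporter of short peptides. In the CD8 T class it was below that minimum, with 56 against 3 UMIs (15.1 against 1.38 CPM). It stood at 23.5 CPM against 3.43 CPM in B cells, a ratio of 6.85 (4.76 to 10.2), with ratios of 5.65 in naive T cells (3.68 to 9.02), 4.23 in NK cells (2.36 to 8.22) and 10.3 in iNKT-type cells (3.79 to 39.1). Ly6k, of the Ly6 family of membrane-anchored proteins, was higher in B cells (4.74) and naive T cells (2.59). Hspa1b, an inducible heat shock protein, was lower in NK cells (0.229, 0.170 to 0.305) and B cells (0.487), as was Hspa1a in B cells (0.399). In 451 and 329 iNKT-type cells, Gzma, encoding granzyme A, stood at 206 against 32.7 CPM, a ratio of 6.30 (5.07 to 7.91), and Ncr1, an activating NK receptor, at 19.3 against 2.84 CPM (6.79, 3.26 to 16.3). Few cells carried them: Ncr1 was seen in 10 and 3 cells, and Gzma in 48 and 31.

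Other genes named in these classes differed by about 2-fold or more. In B cells B3gnt7 was higher (2.60) and Kcnip1 lower (0.458). In NK cells the lectin-like receptor gene Klri1 (2.91) and the sialyltransferase St6galnac3 (2.09) were higher, and Nkain2 (0.365) and the linker histone H1f3 (0.396) lower. In naive T cells the chemokine Ccl5 was higher (2.37), and Cd40lg (0.474), Camk2b (0.521) and Lamp2 (0.524) were lower. The mix of that class differed, with 400 cells of the CD8 cluster and 572 of the CD4 cluster in WT HFD, against 539 and 447 in WT HFD+HDCA. In CD8 T cells Ms4a6d (2.30), Fcgrt (2.14) and Cdk5rap1 (2.07) were higher, and Ptprk (0.124), Camk2b (0.391) and Oxsr1 (0.395) lower. In iNKT-type cells Ccl4 (5.24) and Hmmr (4.73), a gene of dividing cells, were higher, and Rcan1 (0.388), Cd8a (0.388), Cd8b1 (0.388), Tjp1 (0.424) and Fosl2 (0.432) were lower. Ccl1 (45.8) and Chil3 (0.368) in iNKT-type cells came almost wholly from single cells, which held 98.3% and 100% of the UMIs of the library where each was higher, and single cells held 29.99% of Gzma, 39.5% of Ccl4, 37.5% of Cd8a, 29.1% of Cd8b1, 26.2% of Hmmr, 25.7% of Ncr1, 30.6% of Ptprk and 26.5% of Oxsr1. With cells thinned to an equal depth, the log2 ratio moved by more than 1.5-fold for Ms4a6d (2.58), Fcgrt (0.39), Ptprk (-1.42), Oxsr1 (-0.73), Slc15a2 in NK cells (3.45), Ccl1 (4.68), Ncr1 (3.36), Gzma (3.49), Ccl4 (1.64), Hmmr (at least 0.97, from 0 UMIs in WT HFD), Cd8b1 (-0.29) and Cd8a (2.01, the other direction). Without the cell with most UMIs, WT HFD had 0 UMIs of Chil3, which puts it at 2.30 or higher, the other direction, and Ccl4 was at 1.66.

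**Figure D3:**
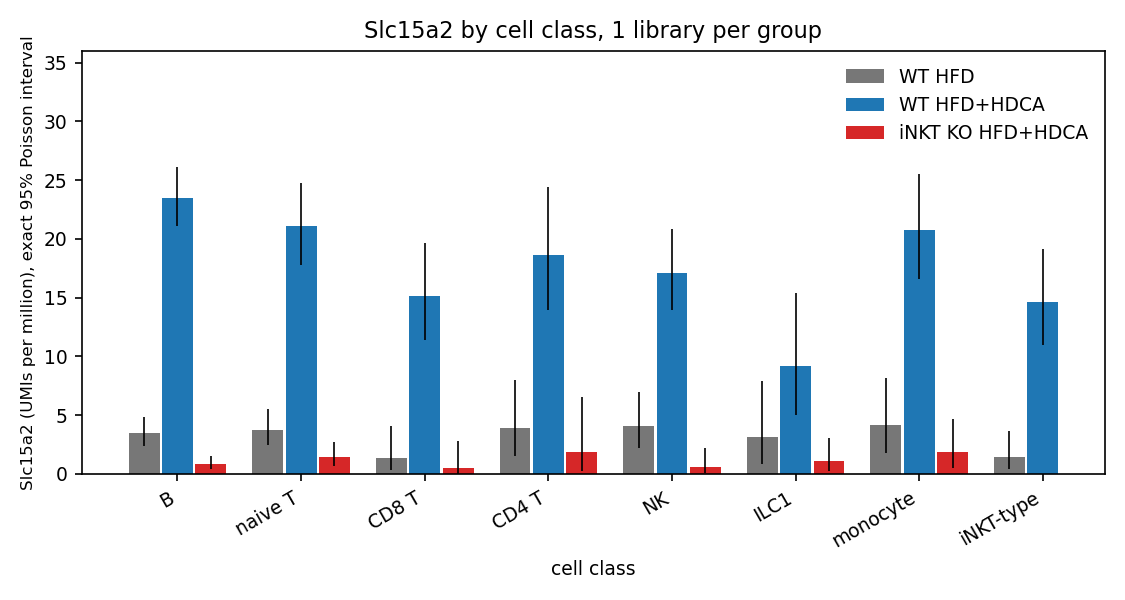
Level of Slc15a2 (y axis, CPM with exact 95% Poisson intervals) by cell class in the 3 libraries; iNKT-type cells are shown for the WT libraries. In B cells it stood at 3.43 in WT HFD, 23.5 in WT HFD+HDCA and 0.799 in iNKT KO HFD+HDCA.

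By gene list, iNKT-type cells of WT HFD+HDCA had higher cell cycle, cytotoxic and type I interferon genes than those of WT HFD. The cell cycle list had a median log2 ratio of 0.36 (0.20 to 0.54), with 14 of 15 measured members higher, among them Ccnb2 (3.03), Birc5 (2.13) and Mki67 (1.97). The cycling class held only 16 iNKT-type cells of WT HFD+HDCA and 5 of WT HFD. Members read in the same few cells are not independent, which the interval leaves out. Of 17 cytotoxic effector genes 15 were higher (median 0.25), and of 23 type I interferon genes 16 were higher (median 0.22), such as Isg20 (1.86). The naive or central memory list was lower, with 10 of 11 members lower and a median of -0.18, including S1pr1 (0.701) and Tcf7 (0.799). The iNKT type 1 list had 10 of 14 members higher (median 0.13), and the inhibitory receptor list 10 of 11 (median 0.26). Genes of other cell types were higher beside them, with MHC class II at a median of 0.58 (6 of 9 higher) and transcripts of other liver immune cells at 0.33 (3 of 4 higher).

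In other αβ T cells, genes of inflammatory cytokines and chemokines were lower under HDCA in WT. All 10 measured members were lower, with a median of -0.81 (-1.20 to -0.59), including Ccl3 (30.5 against 93.0 CPM, ratio 0.328) and Ccl4 (114 against 274 CPM, 0.417). The inhibitory receptor list was lower in 10 of 14 members (median -0.21), with Havcr2 at 0.232 and Lag3 at 0.379. Without the largest clonotype of WT HFD alone, chosen after seeing the data, the cytokine median was -0.36 and the inhibitory receptor median 0.29, the other direction. Without that of each library they were -0.35 and 0.24, so the inhibitory receptor difference rested on that clone and the cytokine difference in part. The lists of other liver immune cells (median 1.01, 6 of 10 higher) and Kupffer identity (0.46, 4 of 4) had higher medians in these T cells. Summed, the transcripts of other liver immune cells were not higher, at 927 CPM in WT HFD and 912 CPM in WT HFD+HDCA.

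Heat shock genes were lower under HDCA in most lymphocyte classes of WT mice. Their median was -0.30 in naive T cells (11 of 11 lower), -0.32 in CD4 T cells (10 of 11), -0.21 in NK cells (10 of 11), -0.21 in CD8 T cells (10 of 11) and -0.15 in B cells (9 of 11), with percentiles from 0 to 0.01 among random lists in naive T, CD4 T and B cells. In iNKT-type cells 8 of 11 were lower (median -0.12). Dnajb1, a partner of inducible heat shock protein, stood at 0.728 in naive T cells and 0.772 in CD8 T cells. Immediate early genes, which respond to tissue dissociation, were lower beside them in NK cells, 18 of 20 members at a median of -0.19, such as Fosb (0.767) and Jun (0.798), in naive T cells (15 of 19, -0.18), CD4 T cells (16 of 20, -0.098) and other αβ T cells (17 of 20, -0.099).

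Monocytes of WT HFD+HDCA had higher MHC class II and cholesterol synthesis genes and lower inflammatory genes than those of WT HFD. All 10 MHC class II genes were higher (median 0.56), including H2-Aa (849 against 548 CPM, 1.55) and H2-Ab1 (1.502). In the cholesterol synthesis list 16 of 17 genes were higher (median 0.52), including Idi1 (1.99, 1.16 to 3.60). Inflammatory cytokine and chemokine genes were lower in 10 of 13 (median -0.32), including Tnf (75.8 against 137 CPM, 0.552), Ptgs2 (0.569) and Ccl4 (0.618). The cytotoxic list, which shares Tnf and Ccl4 but otherwise holds mostly genes of T and NK cells, was lower beside them (median -0.64, 12 of 13). Whether less material of such cells in the droplets lowered Ccl4 was not tested. All 12 measured cell cycle genes were higher (median 1.48), although Stmn1 stood at only 2.57 and 15.5 CPM and most members had few UMIs. With at least 100 UMIs per gene that median was 0.48. The list of other liver immune cells was higher in these monocytes too (median 0.22, 6 of 9 higher). It holds Lyz2, the leading gene of their cluster, and shares Cd74 with MHC class II, so it does not mark foreign material here. Immediate early genes were lower in these monocytes (-0.14, 15 of 20 lower).

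In CD8 T cells of WT mice, 12 of 18 cytotoxic genes were higher under HDCA (median 0.21), such as Ccl4 (1.76) and Gzmm (1.73), while Gzma was lower (0.539), and 15 of 17 interferon gamma genes were higher (median 0.19). Naive T cells had higher iNKT type 1 genes (median 0.93, 12 of 12 higher) and cytotoxic genes (median 0.53), with Nkg7 at 388 against 242 CPM. The naive class joined a CD8 and a CD4 cluster whose shares differed between libraries. In the CD4 cluster alone the iNKT type 1 median was -0.078, the other direction, and in the CD8 cluster alone it was 0.46. In B cells, 24 of 27 oxidative phosphorylation genes were higher by a small amount (median 0.08). Hepatocyte transcripts were also higher in the B cells of WT HFD+HDCA, at 14.7 CPM against 4.07 CPM in WT HFD and 6.22 CPM in the knockout.

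The knockout under HDCA was compared by the ratio of iNKT KO HFD+HDCA to WT HFD+HDCA. Slc15a2 was lower in the knockout, at 0.799 against 23.5 CPM in B cells, a ratio of 0.0340 (0.0154 to 0.0654), 0.0355 in NK cells (0.00424 to 0.132) and 0.0685 in naive T cells (0.0307 to 0.134). NK cells of the knockout had more Zfp683 (ENSMUSG00000049410), encoding the residency factor Hobit, at 34.4 against 2.42 CPM (14.2, 8.12 to 26.8), although their larger cluster alone had 3 against 8 UMIs (0.904, 0.154 to 3.77). They also had more Lgals3 (ENSMUSG00000050335), encoding galectin-3, at 323 against 22.998 CPM (14.05, 11.7 to 16.95). Hspa1b was higher in NK cells (6.44, 4.91 to 8.55) and B cells (4.42, 3.94 to 4.98), and Hspa1a in B cells (4.55). Dok2 (ENSMUSG00000022102), an adaptor of receptor signalling, was higher in B cells (8.84, 5.79 to 14.1).

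Other genes named for the knockout included several that lie, like Traj18, on chromosome 14 of the GRCm38.p6 assembly. These were Dok2, Lgals3 in NK cells and CD8 T cells (2.69), Tmem254 in NK cells (0.276) and CD8 T cells (0.330), Abhd4 in B cells (0.308) and Rpgrip1 in naive T cells (0.243). Elsewhere in the genome, Il9r was lower in B cells (0.301), Cdk5rap1 in NK cells (0.239) and CD8 T cells (0.321), Ccl3 in CD8 T cells (0.399), and Dynlt2a2, which has no match in that assembly's table, in naive T cells (0.296). Camk2b (2.75) and Ikzf2, encoding Helios (2.63), were higher in CD8 T cells, and Il1rapl1 (3.36), Cd79a (3.44) and H2-Ab1 (3.31) in naive T cells. Cd79a and H2-Ab1 are B cell genes, and single cells held 23.9% and 17.3% of their UMIs in the knockout. The NK class joined 2 clusters, and in the larger of them alone the log2 ratio of Lgals3 was 3.10 in place of 3.81. In the CD4 cluster of naive T cells alone, that of Slc15a2 was -5.27 and that of Rpgrip1 -2.91, and with equal weight per cell that of Zfp683 in NK cells was 4.44. With cells thinned to an equal depth Slc15a2 in NK cells had 0 UMIs in the knockout, a log2 ratio of -2.96 or lower, and Dynlt2a2 was at -2.70 in place of -1.76.

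Interferon-response genes were lower in the knockout over all cells, but not in every class. Over all cells, 24 of 24 type I interferon genes were lower, with a median log2 ratio of -0.41 (-0.45 to -0.35), and 20 of 20 interferon gamma genes, with a median of -0.20 (-0.24 to -0.17). These medians also follow the shares of the cell classes, which differed between the libraries. In other αβ T cells 20 of 23 type I interferon genes were lower (median -0.33), including Rsad2 (0.555), Mx1 (0.574) and Ifit3 (15.01 against 26.02 CPM, 0.577). The median was -0.36 in NK cells (17 of 19 lower), with Usp18 at 0.586, -0.28 in monocytes (22 of 24 lower), with Ifit3b at 0.368, and -0.11 in B cells (16 of 22 lower). In CD8 T cells it was 0.01 and in naive T cells -0.065 (9 of 20 higher). Interferon gamma genes were split in NK cells (9 of 17 higher, median 0.0087), CD8 T cells (9 of 18, -0.0060) and B cells (8 of 17, -0.017). With at least 100 UMIs per gene the NK median was -0.16. A cluster of interferon-responding cells, led by Ifit3 and Isg15, made up 0.860% of WT HFD, 1.16% of WT HFD+HDCA and 0.543% of the knockout.

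Other αβ T cells of the knockout had lower activation and effector genes than those of WT HFD+HDCA. Activation genes were lower in 13 of 16 members (median -0.31), including Egr3 (0.247) and Tnfrsf4 (0.586), while Cd40lg was higher (1.42). Cytotoxic genes were lower in 15 of 18 (median -0.22), with Gzmm at 0.514 and Cx3cr1 at 0.541, but Gzmb (250 against 89.4 CPM, 2.80) and Gzma (1.65) were higher. The iNKT type 17 list was lower in 8 of 11 members (median -0.93), including Il17a (0.297, from 9 UMIs in 3 cells against 43 in 12). The type 10 and follicular list was lower in 8 of 10 (median -0.39), and NF-kB feedback genes in 12 of 13 (median -0.19). Cytokine and chemokine genes were lower in 7 of 8 (median -0.35), among them Cxcl10 (0.637). This pool joins T cell classes whose shares differed between the libraries. Within classes the activation median was -0.050 in CD4 T, -0.054 in CD8 T and -0.25 in naive T cells, and type 10 and follicular genes were higher in 7 of 10 in CD4 T cells (median 0.15), the other direction. MHC class II genes, which belong to other cell types, were higher in 9 of 10 members in the pool (median 0.25). In CD8 T cells 12 of 18 cytotoxic genes were lower (median -0.17), including Ifng (0.671).

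NK cells of the knockout had lower activation genes, and their residency genes differed through 1 cluster. Of 13 activation genes 12 were lower (median -0.59), including Egr1 (0.573) and Tnfrsf9 (0.621), and in the larger NK cluster alone the median was -0.17. Residency genes included Itga1 (4.26) and Cxcr6 (2.93) beside Zfp683, though Xcl1 was lower (0.580) and 5 of 13 members were lower (median 0.28). The cluster rich in Klrg1 held 209 of 623 knockout NK cells against 39 of 958, and in the larger cluster alone the residency median was -0.057, the other direction, with Itga1 at 0.425 and Cxcr6 at 1.20. MHC class II genes were higher in these NK cells (median 0.61, 7 of 9 higher), and transcripts of other liver immune cells lower (-0.36, 3 of 5). The sum of the latter took the other direction in NK cells clustered without the cell filter, chosen after seeing the data. It was 250 CPM in the knockout against 164 CPM in WT HFD+HDCA. ILC1 had lower naive or central memory genes in all 10 members (median -0.49), with S1pr1, a receptor for exit from tissue, at 0.251. Monocytes had lower MHC class II genes in all 10 (median -0.40), including H2-Eb1 (0.694) and Cd74 (0.748), and lower interferon gamma genes in 17 of 20 (median -0.33), including Gbp5 (0.546). The list of other liver immune cells was lower in them too (median -0.19, 7 of 9 lower). It holds monocyte genes such as Lyz2 and shares Cd74 with MHC class II. Immediate early genes were higher in these monocytes (0.15, 15 of 20 higher). Their cell cycle list was lower in 11 of 12 members (median -0.87, or -0.30 with at least 100 UMIs per gene). B cells had slightly lower MHC class II genes in all 10 members (median -0.10, percentile 1.84). Mitochondrial transcripts were higher in 12 of 13 members in B cells (median 0.12), CD8 T cells (0.26) and other αβ T cells (0.14) of the knockout, and the mitochondrial share of UMIs was 1.71% against 1.47%.

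**Figure D4:**
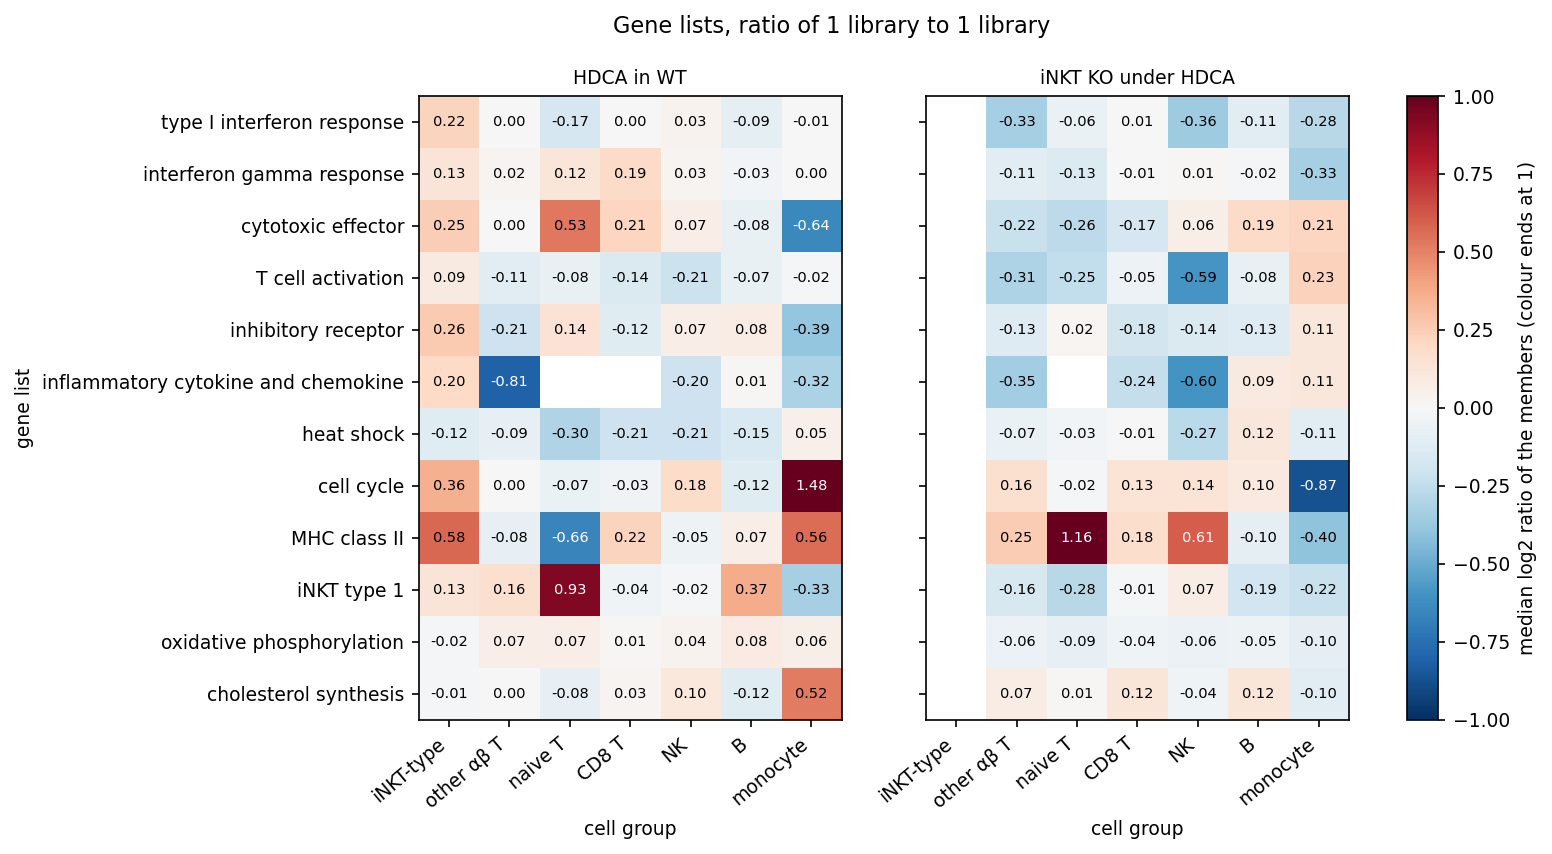
Median log2 ratio of the measured members of 12 gene lists (y axis) in 7 cell groups (x axis) for HDCA in WT and for the knockout under HDCA; blank squares had fewer than 5 measured members or no iNKT-type cells. The type I interferon medians for the knockout were -0.33 in other αβ T cells, -0.36 in NK cells and -0.28 in monocytes.

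Receptors for bile acids and incretins were rare in all 3 libraries. Glp1r, the receptor for GLP-1, had 47 UMIs in WT HFD, 12 in WT HFD+HDCA and 9 in the knockout. In WT HFD 37 of the 47 lay in the largest clonotype, and there were 0 in 329 and 451 iNKT-type cells, which allows up to 1.07 and 0.827 CPM. Gpbar1 had 4, 1 and 0 UMIs (the 0 allows up to 0.0698 CPM), Nr1h4, the bile acid receptor FXR, had 3, 2 and 1, and Ppara had 5, 3 and 5. These counts are too few to compare levels of Gpbar1, Nr1h4 and Ppara. Cd1d1, which presents lipid to iNKT cells, was at 21.6, 21.1 and 23.7 CPM.

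Cytokine genes differed by cell type. Ifng in iNKT-type cells stood at 213 CPM in WT HFD (196 to 231) and 249 CPM in WT HFD+HDCA (233 to 265). In other αβ T cells it was at 65.4, 89.1 and 54.9 CPM, and in NK cells at 264, 175 and 146 CPM, against 0.643, 0.751 and 0 CPM in B cells, where 0 allows up to 0.266 CPM. Il4 in iNKT-type cells was at 96.0 and 97.0 CPM in the WT libraries. In other αβ T cells Il4 was higher in the knockout, at 9.84 CPM (8.30 to 11.6), than in WT HFD+HDCA, at 2.52 CPM (1.88 to 3.30), and its level in WT HFD was 1.46 CPM (0.901 to 2.22). Il10 in other αβ T cells was at 9.70, 4.65 and 1.58 CPM, but in WT HFD 104 of its 140 UMIs lay in the largest clonotype. Without the largest clonotype of each library, chosen after seeing the data, it was at 2.63 (1.84 to 3.63), 4.64 (3.75 to 5.67) and 1.61 CPM (1.02 to 2.42). The knockout stayed below WT HFD+HDCA, and the direction of the summed level for HDCA in WT turned. That turn rests on few cells. Il10 was seen in 55 of 1817 such cells of WT HFD, 33 of them in the clone, and in 29 of 2618 of WT HFD+HDCA. In the CD4 T class of WT HFD+HDCA a single cell held a large part of its UMIs. Il17a had 32, 96 and 143 UMIs over all cells, in 8, 23 and 21 cells, or 0.780, 1.49 and 3.33 CPM. Over all cells it was thus higher in the knockout, the other direction from other αβ T cells. Tnf was at 33.4, 29.2 and 27.0 CPM.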

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

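All tests of explanations in this part were chosen only after the results were seen.

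Some gene lists went in opposite directions in different cell classes of the same comparison. For HDCA in WT, MHC class II genes had a median log2 ratio of 0.56 in monocytes and -0.66 in naive T cells, cytotoxic genes 0.53 in naive T cells and -0.64 in monocytes, and inhibitory receptor genes 0.26 in CD4 T cells and -0.39 in monocytes. For the knockout under HDCA, MHC class II genes stood at 1.16 in naive T cells and -1.53 in CD4 T cells, activation genes at 0.23 in monocytes and -0.59 in NK cells, and cytotoxic genes at 0.21 in monocytes and -0.26 in naive T cells. Transcripts of other liver immune cells moved with MHC class II in CD4 T cells (-0.82 for HDCA, -0.52 for the knockout) and in naive T cells of the knockout (0.80), but not in naive T cells for HDCA in WT (0.12, 2 of 4 higher). Both lists hold Cd74, so they are not independent. Whether the lists in T cells reflect material of other cells was not tested. The differences between classes were not tested.

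The libraries also differed in 2 unnamed clusters, whose cells were compared above only as part of wider groups, such as all cells and other αβ T cells. Cluster 25, with Prss34, Mpo and the progenitor marker Cd34 among its leading genes, held 71 cells of WT HFD+HDCA (0.734%), 11 of WT HFD (0.178%) and 10 of the knockout (0.147%). Cluster 26, led by Gzmk and Pdcd1, held 65 cells of WT HFD (1.05%), 5 of WT HFD+HDCA (0.0517%) and 11 of the knockout (0.161%).

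Genes that differ between the knockout and the WT library under HDCA lay on the chromosome of Traj18 more often than genes in general. In B cells, 15.6% of the 32 genes at least 2-fold apart were on it (5.28% to 32.8%; Tmem254, Lgals3, Gm26782, Abhd4 and Dok2), against 3.45% of measured genes. The share was 17.5% in NK cells, 18.2% in naive T cells and 26.7% in CD8 T cells. For HDCA in WT it was 0 of 10 genes in B cells (up to 30.8%), 0 of 11 in NK cells, 1 of 10 in naive T cells (0.253% to 44.5%) and 1 of 12 in CD8 T cells (0.211% to 38.5%), intervals that overlap those of the knockout. Free RNA that differs between the libraries would give B cells of any depth like counts. For the pooled UMIs of Tmem254, Gm26782 and Abhd4, higher in WT HFD+HDCA, the tables argue against it: the deepest B cells held 1.83 times the UMIs of the shallowest (1.55 to 2.17), above the interval for myeloid transcripts (0.685 to 1.46). Tmem254 dominates that pool, with 623 UMIs in these B cells against 169 and 114 for Gm26782 and Abhd4, which were not tested singly. For Lgals3 and Dok2, higher in the knockout, the pooled ratio was 1.97 (1.64 to 2.37), but its interval meets that of myeloid transcripts there (0.985 to 1.81), so free RNA stays open for them in B cells. DNA carried along with the targeted Traj18 locus may explain genes on that chromosome. In B cells free RNA cannot be told apart from it for Lgals3 and Dok2, nor for Gm26782 or Abhd4 singly. Such DNA leaves the genes elsewhere, such as Slc15a2, open.

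Slc15a2 was higher in WT HFD+HDCA than in either other library, at 19.6 CPM over all cells against 3.39 in WT HFD and 1.23 in the knockout. HDCA acting alike in both genotypes from the same baseline would put the knockout above WT HFD, but the ratio of knockout to WT HFD was 0.364 (0.260 to 0.503). Free RNA in the droplets would give cells of any depth like counts, whereas the deepest B cells held 2.05 times the Slc15a2 UMIs of the shallowest (1.56 to 2.72), near their depth ratio of 1.81, while myeloid transcripts had 59 UMIs at both ends. A difference between the animals or libraries other than HDCA stays open, because 7 of 8 classes shared the higher level and WT HFD+HDCA had 1 library. An effect of HDCA that needs iNKT cells may be the biological alternative. Alone and from the same baseline, it would put the knockout level with WT HFD, and the ratio of 0.364 lies below that. Joined with another difference between the libraries, it cannot be told apart from such a difference.

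Cluster 26 was mostly made of WT HFD cells through 1 expanded T cell clone. Of its 65 WT HFD cells, 95.4% (87.1% to 99.0%) belonged to the largest clonotype of that library. Whether the cell state was also more frequent in WT HFD outside the clone stays open. The clone left 3 cells there against 5 in WT HFD+HDCA, a ratio of shares of 0.953 (0.148 to 4.90), too few to decide, against 20.4 with the clone. The clone expressed Glp1r in 24 of its 76 kept cells (31.6%) and Il10 in 33 (43.4%). Against these, 0.621% of the CD8 T class of WT HFD had Glp1r and 4.66% Il10, and B cells had 0% and 0.0488% (0 allows up to 0.146%), at median depths of 8293.5, 5722 and 4410.5 UMIs. Whether diet or chance expanded the clone was not tested.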

How the results depend on the processing

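Settings named here as added were chosen only after the results were seen. Of 678 values of 149 results under alternative settings, 614 stayed within the counting interval of the reported value, 55 moved beyond it and 9 took the other direction from a value whose interval lay on 1 side of no difference. TCR shares stayed in 17 of 20, class ratios in 79 of 85, clonal expansion in 9 of 10, gene lists in 118 of 123, and named genes in 280 of 300. With added settings, 12 of 23 list, 83 of 93 gene, 15 of 18 free RNA and 1 of 6 clonal values stayed. Of the 27 named-gene values that moved, 19 came closer to 0 and 8 went further, all 27 in the same direction. Leaving out the cell filter kept the same αβ T cells, so 12 free RNA values could not move and are not counted. With NK and B cells clustered without it (added), other immune transcripts in NK cells of WT HFD+HDCA were at 164 CPM, B cell transcripts there at 162 CPM and haemoglobin in B cells of WT HFD at 314 CPM. No paired analysis was possible because each group had 1 library.

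With at least 3 UMIs per contig the knockout had 0% iNKT-type cells and 7.01% of chains at TRAJ19 or higher, and with each distinct CDR3 counted once 7.84%. Without drawing down, 20.6% of other T cells of WT HFD+HDCA were in clonotypes, because more cells were counted. Without the largest clonotype of each library (added), clonotypes of 5 or more held 8.12%, 6.996% and 11.2% of the 3 libraries, and those of 2 or more 15.2% of WT HFD and 19.8% of the knockout. With each library clustered alone, the CD8 T ratio for HDCA was 0.906, and the knockout ratios were 0.930 for CD8 T cells, 0.982 for monocytes and 0.690 for B cells, the other direction. At resolution 0.5 the CD8 T ratio for HDCA was 0.948, and by marker UMIs the NK ratio for the knockout was 1.14. These CD8 T ratios for HDCA and this NK ratio lie across 1 from reported values of 1.14 and 0.924, whose intervals include 1, and count as moved.

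With at least 100 UMIs per gene, which leaves fewer genes, medians were -0.16 for type I interferon in NK cells of the knockout, 0.48 and -0.30 for the cell cycle in monocytes in the 2 comparisons, and 0.48 for iNKT type 1 genes in naive T cells under HDCA. TMM factors gave -0.13 for MHC class II in B cells of the knockout.

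Among genes of iNKT-type cells, Cd8a took the other direction when cells were thinned (2.01) or weighted alike (0.26), and Chil3 without its top cell (added), where 0 UMIs in WT HFD leave 2.30 as a lower bound. Without the largest clonotype of each library, or of WT HFD alone (both added), other αβ T cells under HDCA had medians of 0.31 and 0.34 for cytotoxic, 0.24 and 0.29 for inhibitory receptor (the other direction) and -0.35 and -0.36 for cytokine genes. In cluster 2 alone (added), NK cells of the knockout had activation genes at -0.17 and residency genes at -0.057, the other direction. For naive T cells (added), iNKT type 1 genes under HDCA were at 0.46 in cluster 5 and -0.078 in cluster 6, and at 0.28 for the knockout in cluster 6, the other direction for both values from cluster 6. Where no construction is named, the cause was not tested. Depth limits what counts of a few UMIs per class can show, such as Gpbar1 and Nr1h4.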

Other observations

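In this part the count of innate-like T cells outside the iNKT type and the NK cells clustered without a cell filter were chosen only after the results were seen. The knockout had more αβ T cells outside the iNKT type in the clusters that iNKT-type cells fill in WT, although the clusters as a whole were not larger. Cluster 9 held 3.65%, 3.65% and 3.24% of the 3 libraries and cluster 14 held 3.26%, 2.57% and 1.34%. In cluster 9, led by Cxcr6, Zfp683 and Il4, T cells with both chains and no iNKT-type chain numbered 37 in WT HFD (0.6001% of kept cells), 47 in WT HFD+HDCA (0.486%) and 160 in the knockout (2.35%), a knockout ratio of 4.83 (3.47 to 6.84). Without the largest clonotype the ratio was 3.69 (2.61 to 5.28). In cluster 14 they numbered 17, 37 and 74, a knockout ratio of 2.84 (1.89 to 4.34). Such cells of cluster 9 had Il4 at 52.2, 146 and 119 CPM and Zbtb16, encoding the iNKT factor PLZF, at 52.2, 163 and 73.01 CPM. Il4 was seen in 0.715%, 0.879% and 4.06% of other αβ T cells, and in 0.0488%, 0.0611% and 0% of B cells (0 allows up to 0.114%), at median depths of 7094, 7120 and 7019 UMIs in the T cells and 4410.5, 4303 and 4121 in the B cells. No explanation was tested.

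CD4 T cells under HDCA in WT had higher type 10 and follicular genes in 8 of 10 members (median 0.63), among them Il10 (6.51, where 1 cell held 38.8% of its UMIs) and Pdcd1 (1.88). Patrolling monocytes of the knockout had lower iNKT type 1 genes in 13 of 14 members (median -1.69) and lower cytotoxic genes in 13 of 15 (-0.84). HDCA in WT had both higher in these monocytes (0.64 and 0.79). These are genes of T and NK cells, so material of such cells in the droplets stays open. The knockout's patrolling monocytes also had higher immediate early genes in 20 of 20 (median 0.23). Over all cells, HDCA in WT and the knockout under HDCA had medians of 0.36 and -0.42 for Kupffer identity genes, -0.02 and -0.34 for iNKT type 2 genes, 0.05 and -0.22 for anti-inflammatory genes, and 0.05 and 0.03 for genes of lipid-associated macrophages. PPAR target genes stood at 0.04 and 0.01, bile acid and incretin receptors at -0.15 and 0.09, and glycolysis at 0.07 and -0.09. All of these medians over all cells follow cell shares as well as levels per cell. iNKT-type cells, nearly absent in the knockout, held 352 of the 500 Il4 UMIs of WT HFD+HDCA. A lower iNKT type 2 list in the knockout therefore says nothing about other cells.

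The lists used to look for free RNA differed between the libraries. Over all cells, hepatocyte genes had medians of 1.22 and -1.10 in the 2 comparisons, haemoglobin genes 0.27 and -8.50, and transcripts of other liver immune cells 0.26 and -0.40. The last list holds genes that sequenced cells express themselves, such as Lyz2 in monocytes and Igkc in plasma cells. Over all cells it therefore also follows cell shares and is no measure of free RNA. Haemoglobin had 2947, 5552 and 10 UMIs in the 3 libraries, but 2 cells in each WT library had 50 or more, the top ones 2062 and 2834, and the top 10 cells held 99.97% and 99.3%. In NK cells transcripts of other immune cells were at 226, 563 and 257 CPM, although WT HFD+HDCA stood at 164 CPM over 952 in place of 958 NK cells when clustered without a cell filter. The knockout stood at 250 CPM there, so the direction between these 2 libraries turned. Hepatocyte transcripts in NK cells were at 19.6, 15.2 and 17.03 CPM. In NK cells of the knockout, heat shock genes had a median of -0.27 although Hspa1b was higher (6.44).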
